A study of Rattus norvegicus with 15 samples.

How the data were processed

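Liver RNA of 15 female Wistar rats was hybridised with Cy3 to one-colour Agilent rat arrays, 1 array per rat and no pooling, per the labels' protocols. Rats received fipronil at 3 mg/kg per day by mouth for 14 days (n = 8) or the vehicle (n = 7), per the labels. RNA integrity numbers were above 8.7 and 1 microgram of RNA was labelled, per the labels' protocols. The slide of each array was read from the deposited file of that array. Each of the 4 slides held rats of both groups.

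The deposited array files give spot intensity values written by Agilent Feature Extraction 9.5.3.1 from a GenePix scan, per the file headers. The processed intensity was background subtracted with spatial detrending, multiplicatively detrended and replaced by a surrogate where a spot was dim, and it was not normalized between arrays, per the file headers. Mean and median spot intensity and the median local background carry no correction, per the file headers. The deposited files also mark each spot with 0 or 1 flags for saturation, for signal well above background and for outlier spots, per the file headers. The deposited series value table holds log2 values for 22244 probes, all of which matched a probe of the array files. Per the labels, the authors' processing used limma and Feature Extraction 9.5. Column medians of that table lay between 7.651 and 7.661 and its highest value was 16. Its Spearman correlation across probes was at least 0.99999 with the median spot intensity of the same array and 0.993 to 0.998 with the processed intensity; probes are not independent replicates. From these values the table was read as log2 median intensity without background subtraction, quantile normalized. Its scale, centring and direction are thereby known, whereas the rule by which its probes were chosen is not stated and stays unknown.

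Probe coordinates are those of build rn4, per the file headers. No genome of that build was at hand, so the exon or untranslated region under a probe is not given and probe sequences were not searched against related genes. Gene symbols came from a RefSeq table of assembly GRCr8, used for names only. Of 41012 probes, 10768 were named by accession, 276 by another accession of the probe, 4993 by symbol, 3341 by synonym, 1031 by gene number, 1275 by a symbol in the description and 7 by a P450 name in the description, and 1575 kept the name in the file. Another 17745 probes had no name, and 1 was left unnamed because its name and description gave different P450s.

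Spots marked as outliers were left out, the spots of a probe were averaged, and log2 processed intensity was expressed relative to the 75th percentile of all non-control probes of its array. That log2 value is called signal. A gene measured by several probes was represented by the brightest, and probes without a symbol were kept as features of their own. This gave 36073 features. Features well above background on at least 7 arrays were tested, which left 20056, of which 12009 had a symbol. Features missing on more than 3 arrays were left out, 22 in all. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, at a Benjamini-Hochberg adjusted p under 0.05. SD is the spread over rats, SE the error of the fitted log2 difference, and intervals are at the 95% level. A gene above background on no vehicle array was given a lower bound for its fold, taken against the lowest signal among probes well above background on each vehicle array, or the probe's own signal where that was higher. Slides were compared by limma's F test in a fit with group and slide.

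Gene lists were compared with the remaining features by limma's camera with a preset correlation of 0.01, two-sided and adjusted over the lists with at least 5 measured members, with an estimated correlation as an alternative. Fry, also an alternative, asked whether a list's genes moved one way on balance, without comparing them with other features. The 83 features with a missing value on any array did not enter these tests. There were 32 lists, 24 of pathways and 8 of cell types, and 33 of their 604 places had no probe. The pathway lists were CAR and PXR target P450s, AhR targets, glucuronidation, sulfation, glutathione conjugation, other phase I and NADPH or haem supply, hepatic transporters, thyroid hormone transport, deiodination and receptors, T3-induced liver genes, nuclear receptors and liver transcription factors, NRF2 targets, PPARalpha targets and fatty acid oxidation, cholesterol synthesis, fatty acid and triglyceride synthesis, bile acid synthesis and handling, glucose and amino acid metabolism, cell cycle, endoplasmic reticulum stress, acute phase and inflammation, female-predominant and male-predominant liver genes, circadian clock, and perivenous and periportal hepatocyte genes. The cell type lists held markers of hepatocytes, Kupffer cells and macrophages, stellate cells and fibroblasts, endothelial cells, cholangiocytes, T, B and NK cells, neutrophils and erythroid cells.

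Named genes were the 12 largest rises and 12 largest falls among genes with a symbol past the threshold whose change had the same sign on all 4 slides, up to 3 members past the threshold per list with the largest change or else the member with the smallest p, and a set of fixed genes of drug and thyroid hormone metabolism. This named 74 genes, of which 39 passed the threshold; results of a few of them are withheld from the text. The fixed gene Slco1a4 was not tested in this way because its brightest probe lacked values on too many arrays. Groups, tests, lists, the naming rule and the first group of alternatives below were chosen before the data were examined.

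Array quality measures were compared by exact two-sided permutation tests over all 6435 splits of the rats. Correlations across arrays used deviations from the group means and 100000 permutations. Chance was examined with 100 random splits, and after seeing the data with 100 splits that kept the numbers of both groups on every slide. The first group of alternatives changed the background correction, the scaling, the signal column, the source of values, the filter on dim probes, the treatment of several probes, the slide and replicate terms, the variance model, array weights, the threshold and the set test, and left out each array in turn. Alternatives added after seeing the data were array brightness as a covariate, each slide left out, the dimmest array of each group left out, a slide block with quantile normalization, and features saturated on any array left out. An exact test of each list's mean was also added after seeing the data.

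The steps were tested on simulated data for the comparison of fipronil with vehicle, with 200 features among 19973 changed by known folds. Recovered were 42 of 67 features changed 1.5-fold (62.7%), 65 of 67 changed 2-fold (97.0%) and all 66 changed 4-fold. In all 183 features were called, of which 10 were false and 0 had the wrong direction. A list shifted by 0.5 on the log2 scale was called, and 0 other lists of the 31 were. Simulated features were drawn independently of one another, without differences in slide or brightness. The simulation therefore gives no rate of false calls for lists of correlated genes. The number of arrays limits the precision. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.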

Results

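Messenger RNA was measured in the liver of 15 female Wistar rats aged 2 to 3 months, with 1 one-colour array per rat. Fipronil, a phenylpyrazole insecticide that blocks insect GABA-gated chloride channels, was given by mouth at 3 mg/kg per day for 14 days to 8 rats. The other 7 rats received only the vehicle, an aqueous methylcellulose mixture. The arrays lay on 4 slides, and both groups were present on every slide. Signal is given as log2 intensity relative to the 75th percentile of the same array.

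Arrays of fipronil rats were brighter than those of vehicle rats. The 75th percentile of intensity was 209.9 ± 25.8 (SD, n = 8) with fipronil and 171.5 ± 33.3 (SD, n = 7) with vehicle (exact permutation p = 0.0196, adjusted p = 0.0378 over 5 measures). Probes well above background made up 57.0 ± 1.25% and 54.9 ± 2.15% (exact permutation p = 0.0227, adjusted p = 0.0378). Saturated probes numbered 168.0 ± 17.1 and 134.0 ± 26.8 (exact permutation p = 0.0109, adjusted p = 0.0378). Median background was 43.9 and 43.0 (exact permutation p = 0.474), and outlier spots made up 0.240% and 0.248% (exact permutation p = 0.787). Across probes, the lowest correlation between any pair of arrays was 0.967 and the median was 0.983, with probes not being independent replicates.

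**Figure D1:**
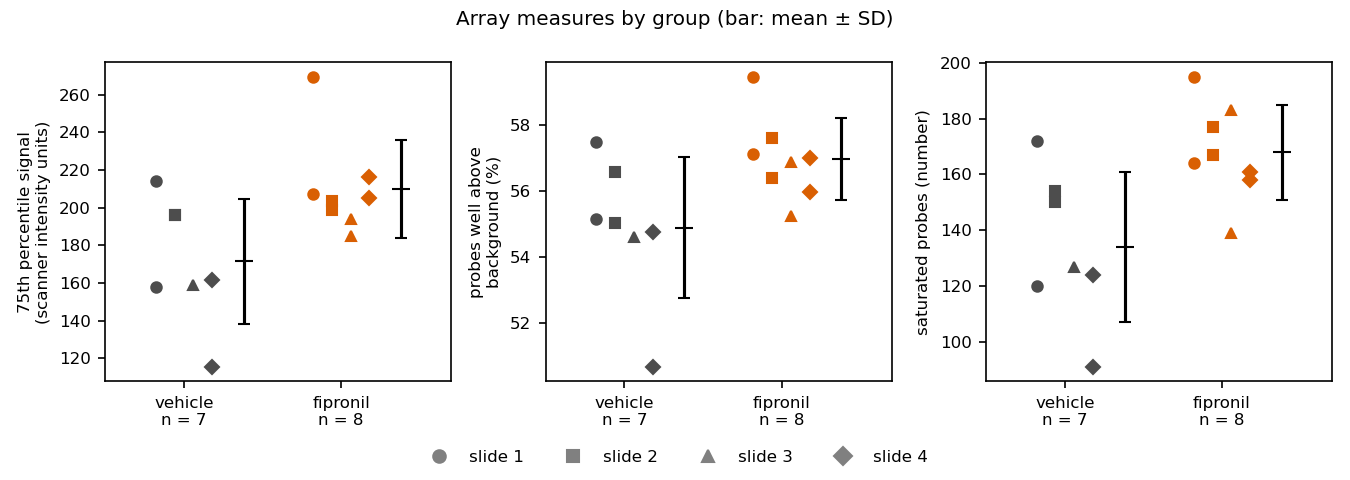
Each point is 1 rat's array, by group, with its 75th percentile intensity, the percentage of probes well above background and the number of saturated probes, and bars give the mean ± SD. The 75th percentile ranged from 115.4 to 269.5 and was higher on average with fipronil (209.9) than with vehicle (171.5).

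The main comparison asked which liver transcripts differed between rats given fipronil and rats given vehicle. Cyp3a23-3a1, a cytochrome P450 of drug and steroid oxidation, rose 16.9-fold (95% interval 12.0 to 23.8), from a signal of 3.92 ± 0.70 (SD, n = 7) to 7.99 ± 0.17 (SD, n = 8). Abcg5 and Abcg8, which form the sterol exporter of the bile canaliculus, rose 12.4-fold and 13.3-fold. Ces2c and Ces2a, carboxylesterases that hydrolyse ester drugs, rose 8.07-fold and 5.93-fold. Among the other largest rises were Ugt2a3, a glucuronosyltransferase (6.11-fold), the organic anion transporter family member Slco1a6 (5.85-fold), the methyltransferase Inmt (6.49-fold), Sbspon (5.90-fold) and Gadd45b, a stress-induced gene (5.54-fold). Cda, cytidine deaminase, and Mme, the peptidase neprilysin, were above background on 8 of 8 fipronil arrays and 0 of 7 vehicle arrays and were at least 4.63-fold and 4.24-fold higher. Abcg8 was above background on 2 of 7 vehicle arrays. With normexp background correction and quantile normalization, every one of these calls was kept, whereas the log2 changes of 5 genes were smaller by over 1.5 times: 1.38 in place of 3.73 for Abcg8, 0.75 in place of 3.62 for Cda, 0.86 in place of 3.29 for Mme, 1.42 in place of 2.70 for Inmt and 1.47 in place of 2.56 for Sbspon. The lower bounds of Cda and Mme hold for background-subtracted signal only. Each of these 12 genes was above the vehicle mean in all 8 fipronil rats, which adds no separate support because the genes were selected on the same rats.

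Among the falls, the potassium channel gene Kcnk2 was 5.91-fold lower (log2 -2.56, SE 0.45, adjusted p = 0.0107) and the sulfotransferase family gene Sult4a1 was 4.88-fold lower (log2 -2.29, SE 0.33, adjusted p = 0.00222). The remaining 10 largest falls were 2.33-fold for the small G protein gene Rasd2, 2.32-fold for Igfbp6, an insulin-like growth factor binding protein, 2.31-fold for Tppp3, 2.29-fold for Dlg5l17, 2.28-fold for Cited4, 2.22-fold for Stmn3, 2.15-fold for the iodide transporter gene Slc5a5, 2.13-fold for the monocarboxylate transporter family gene Slc16a13, 2.03-fold for Angptl2 and 1.89-fold for Gask1a. Slc5a5 was above background on 4 of 8 fipronil and 6 of 7 vehicle arrays, and its call was lost under 24 of 38 alternatives. With normexp background correction and quantile normalization its change was -0.25 (adjusted p = 0.107), and those of Kcnk2, Tppp3, Cited4, Dlg5l17, Igfbp6, Gask1a and Stmn3 were -1.41, -0.71, -0.70, -0.73, -0.66, -0.40 and -0.35, with their calls kept. The call of Slc16a13 was lost under 20 of 39 alternatives, among them slide as a block (-1.09, adjusted p = 0.0501), and that of Tppp3 under 13. A dimmer probe of Rasd2 differed by -0.89 and did not pass (adjusted p = 0.0674). All 8 fipronil rats were below the vehicle mean for each of these 12 genes. The genes were selected on the same rats, so this adds no separate support. The groups did not overlap for Igfbp6, Dlg5l17, Cited4 and Gask1a, and they overlapped for the other falls.

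In limma, 175 of 20056 features (0.873%) passed an adjusted p under 0.05, 111 higher and 64 lower with fipronil, of which 85 and 32 had a symbol. At least a 1.5-fold change was seen in 79 higher and 46 lower features, and at least a 2-fold change in 48 and 26. The median log2 difference of all features was -0.03, and 3517 features had an unadjusted p under 0.05. The change had the same sign on all 4 slides in 173 of the 175. These features were called on the same arrays, so the agreement follows in part from their selection and is no separate replication. The exceptions, Cyp3a62 and Trim37, differed by -0.35 and -0.29 on slide 3, which held 1 vehicle array. Both were chosen after their values were seen. Cyp3a23-3a1 differed by 4.08 (SE 0.23, adjusted p = 4.52e-08), and by 4.08, 3.67, 3.65 and 4.70 on slides 1 to 4; its probe lies on rn4 chromosome 12 from 9567010 to 9567069. Abcg5 differed by 3.64 (SE 0.32, adjusted p = 6.93e-06; rn4 chromosome 6, 8028067 to 8028126). Adjusted p was 9.94e-08 for both Ces2c and Ces2a, 9.52e-06 for Abcg8 and 3.31e-08 for Slco1a6. With array brightness as a covariate, an alternative added after seeing the data, 39 features passed (32 higher and 7 lower), all of them among the 175; the 12 largest rises all kept their call and 4 of the 12 largest falls did (Sult4a1, Igfbp6, Stmn3 and Gask1a). The 8 falls that lost their call there stayed about as large, with wider errors: Kcnk2 -2.17 (SE 0.54), Tppp3 -1.30 (SE 0.30), Slc16a13 -1.20 (SE 0.29), Dlg5l17 -1.10 (SE 0.24), Cited4 -1.09 (SE 0.26), Slc5a5 -1.07 (SE 0.31), Rasd2 -0.98 (SE 0.28) and Angptl2 -0.88 (SE 0.23). The count was 34 without slide 1, 114 without slide 2, 186 without slide 3 and 43 without slide 4. With single arrays left out it ranged from 89 without vehicle replicate 2 to 287 without vehicle replicate 3.

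**Figure D2:**
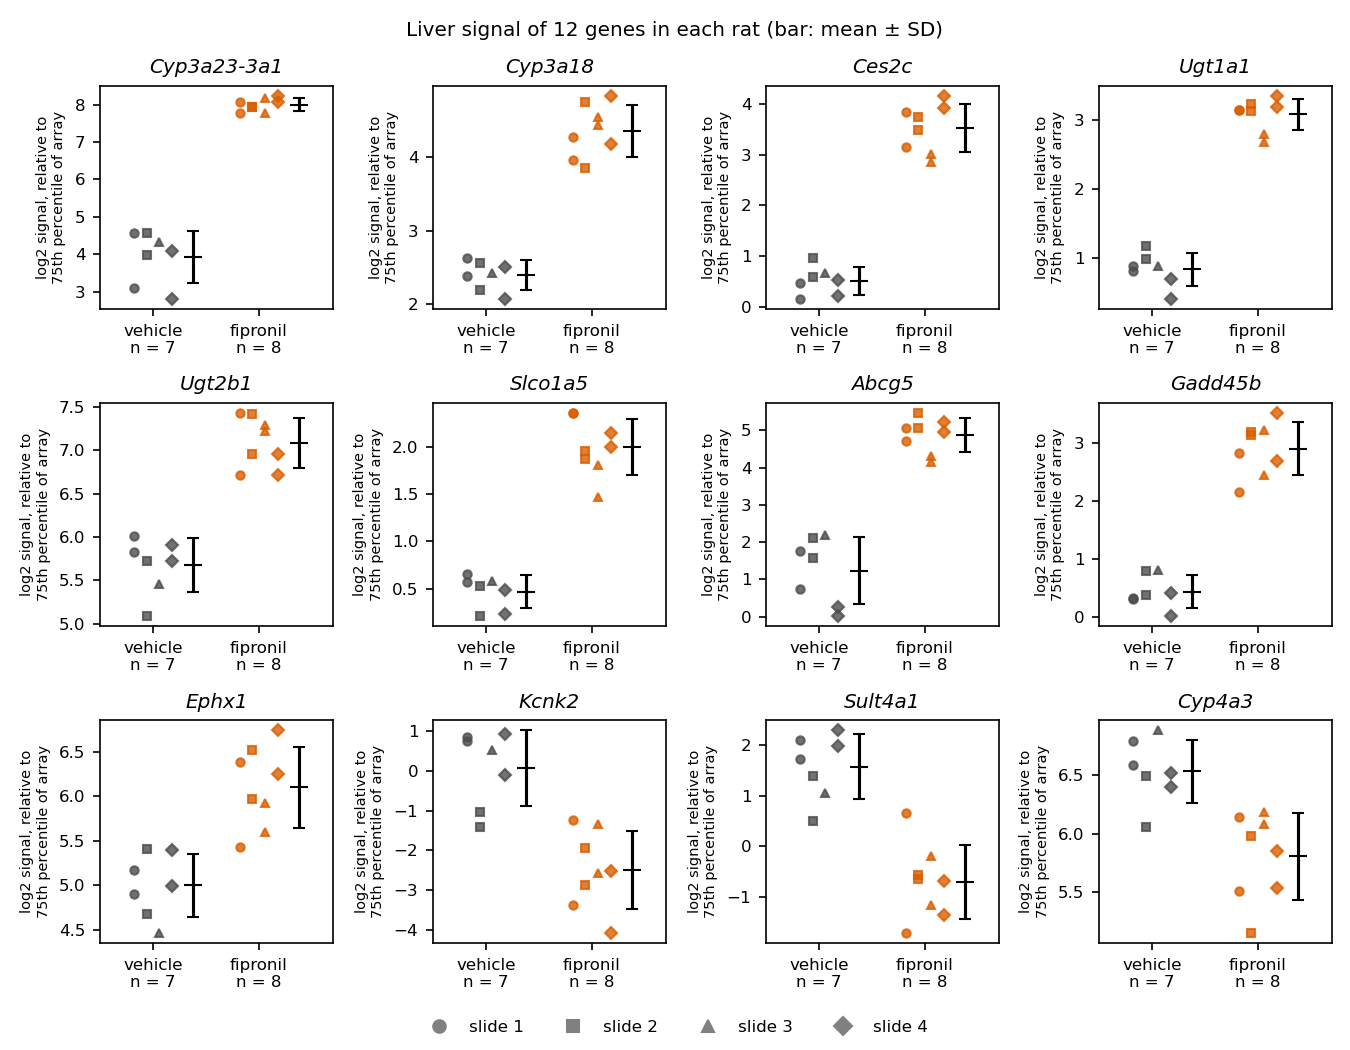
Each panel shows 1 gene, with log2 signal relative to the array's 75th percentile on the vertical axis and the groups on the horizontal axis; points are rats, marker shape gives the slide, and bars give the mean ± SD. Cyp3a23-3a1 stood at 7.99 with fipronil and 3.92 with vehicle, and Kcnk2 at -2.49 and 0.08.

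Among cytochrome P450 genes that the nuclear receptors CAR and PXR are known to induce, 4 of 14 measured members rose and 0 fell. They were Cyp3a23-3a1, Cyp3a18 (3.91-fold, log2 1.97, SE 0.15, adjusted p = 1.00e-06), Cyp3a9 (2.13-fold, adjusted p = 0.0491) and Cyp3a62 (2.01-fold, adjusted p = 0.0330; chosen after its values were seen). All 4 belong to the Cyp3a family, whose enzymes oxidise many drugs and steroids. Cyp3a2, whose enzyme is of the same family, differed by 2.87 and did not pass (adjusted p = 0.0524), being above background on 7 of 8 fipronil and 1 of 7 vehicle arrays. It passed under 9 of 35 alternatives, among them slide as a block (3.06, adjusted p = 0.0379) and array weights (3.21, adjusted p = 0.00893), and its change was 0.61 with normexp background correction and quantile normalization (adjusted p = 0.0759; 0.00509 to 0.372 over the alternatives). Adjusted over the list alone, 7 rose and 1 fell. The list's median log2 change was 0.48 (camera adjusted p = 3.77e-07, adjusted p = 0.0660 with an estimated correlation) and ranged from 0.07 to 0.81 over the alternatives. The call of Cyp3a9 ended with slide as a block (1.03, adjusted p = 0.0513) and with array brightness as a covariate (1.26, adjusted p = 0.158), and over 39 alternatives its adjusted p ranged from 0.0341 to 0.336.

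The Cyp2b genes, classical targets of CAR, gave different results by probe. The brightest probes of Cyp2b1 and Cyp2b2 differed by 0.06 (adjusted p = 0.961) and 0.22 (adjusted p = 0.809), and without vehicle replicate 3 both turned, to -0.28 and -0.09. Over the alternatives they ranged from -0.37 (without slide 2) to 0.93 (mean of the probes) and from -0.22 to 0.70 in the same 2 settings. A second probe of Cyp2b1 rose 3.47-fold, from 0.85 ± 0.44 (SD, n = 7) to 2.65 ± 0.80 (SD, n = 8) (log2 1.80, SE 0.31, adjusted p = 0.00930 with every probe tested). A second probe of Cyp2b2 differed by 1.18 (adjusted p = 0.0604), and it passed with normexp or median intensity and quantile normalization (1.15 and 1.16, adjusted p = 0.0447 for both) and in the authors' table (1.17, adjusted p = 0.0425). A probe of the same gene cluster without a symbol, singled out after its values were seen, rose 7.15-fold (adjusted p = 0.00386). With array brightness as a covariate neither the second Cyp2b1 probe (1.84, SE 0.39, adjusted p = 0.0941) nor the unnamed probe (2.85, SE 0.55 in place of 2.84, SE 0.43, adjusted p = 0.0557) passed, although their changes were as large as without it. The Cyp2b3 probe, also singled out afterwards, differed by -0.15 and was saturated on 3 arrays; the difference was 0.34 with the brightness covariate.

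**Figure D3:**
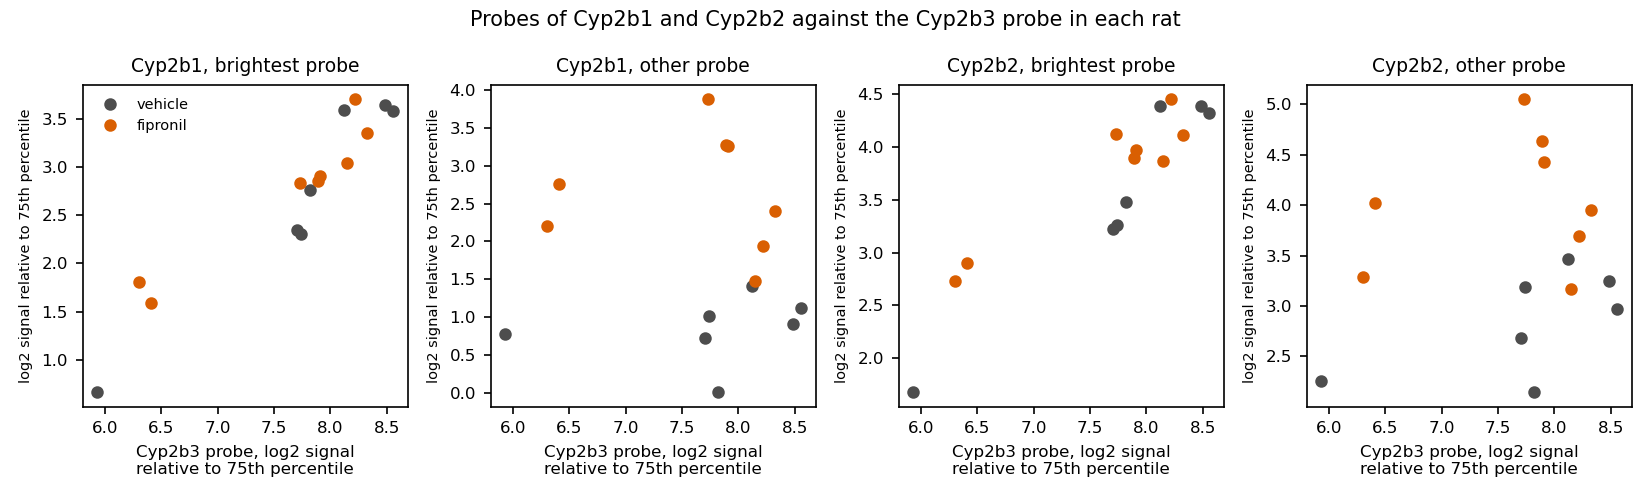
Each point is 1 rat, with the log2 signal of the Cyp2b3 probe on the horizontal axis and that of a Cyp2b1 or Cyp2b2 probe on the vertical axis, both relative to the array's 75th percentile, and colour gives the group. Over deviations from the group means, the brightest Cyp2b1 and Cyp2b2 probes correlated with the Cyp2b3 probe at r = 0.953 and 0.944, and the second probes at 0.04 and 0.36.

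Targets of the aryl hydrocarbon receptor, which responds to planar aromatic compounds, showed no member past the test, 0 of 6. Cyp1a1 differed by 1.32 (adjusted p = 0.451), with 3 of 7 vehicle arrays above background, and ranged from 0.23 (normexp background correction and quantile normalization) to 2.15 (without slide 4) over the alternatives. Cyp1a2 differed by -0.13 (adjusted p = 0.804; -0.22 to 0.05 over the alternatives), where a second probe differed by 0.01. The smallest p of the list belonged to Aldh3a1 (-0.23, adjusted p = 0.222). Adjusted over the list alone, 0 passed. The list's median was -0.07 and its mean 0.17, and camera gave a downward direction (adjusted p = 0.949).

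Glucuronosyltransferases, which attach glucuronic acid to bilirubin, thyroxine, steroids and drugs, rose in part. Of 12 measured members of the glucuronidation list, 5 rose and 0 fell. Ugt1a1, the bilirubin-conjugating enzyme, rose 4.75-fold, from 0.84 ± 0.24 (SD, n = 7) to 3.08 ± 0.23 (SD, n = 8) (log2 2.25, SE 0.12, adjusted p = 3.31e-08). Ugt2a3 rose 6.11-fold, Ugt1a2 3.07-fold and Ugt2b1 2.66-fold (adjusted p = 2.39e-06, 9.94e-08 and 7.34e-05), and Ugt2b35 rose 1.29-fold (chosen after its values were seen). Adjusted over the list alone, 7 rose. The median change was 0.41 (camera adjusted p = 2.98e-12), and the call held with an estimated correlation (adjusted p = 0.00138).

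Other conjugating enzymes gave smaller or mixed changes. Of 13 sulfation genes, Sult1b1, a sulfotransferase that acts on phenols and thyroid hormones, rose 1.71-fold (adjusted p = 0.0227) and Sult4a1 fell; adjusted over the list alone, 1 rose and 1 fell, and the median was -0.21 (camera adjusted p = 0.477). Sult2a1, a hydroxysteroid sulfotransferase, differed by -0.30 (adjusted p = 0.205) and was saturated on all 15 arrays. Of 20 glutathione conjugation genes 0 passed over all genes, with the smallest p for Gstm2 (0.72, adjusted p = 0.0509), which passed under 12 of 39 alternatives, among them slide as a block (0.75, adjusted p = 0.0428), and adjusted over the list alone 5 rose. The median of that list was 0.21 (camera adjusted p = 0.00318, adjusted p = 0.194 with an estimated correlation). The call of Sult1b1 ended with array brightness as a covariate (0.84, adjusted p = 0.119; 0.0109 to 0.236 over the alternatives).

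Among 32 genes of other phase I reactions and NADPH or haem supply, 5 rose and 0 fell, and adjusted over the list alone 5 rose and 1 fell. They were Ces2c, Ces2a, the retinaldehyde dehydrogenase gene Aldh1a1 (2.35-fold, adjusted p = 0.0138), the microsomal epoxide hydrolase gene Ephx1 (2.15-fold, adjusted p = 0.0129) and the aflatoxin aldehyde reductase gene Akr7a3 (1.90-fold, adjusted p = 0.0480). The median change was 0.04 (camera adjusted p = 0.00451, adjusted p = 0.218 with an estimated correlation) and ranged from -0.02 to 0.13 over the alternatives. Por, which passes electrons to P450s, differed by 0.35 (limma adjusted p = 0.305). Alas1, which starts haem synthesis, differed by -0.26 (limma adjusted p = 0.192) and was saturated on 8 of 8 fipronil and 6 of 7 vehicle arrays. At that ceiling a rise of Alas1 could hardly be seen. Of 17 targets of NRF2, a regulator of antioxidant genes, Ephx1 and Akr7a3 rose, both shared with the preceding list; adjusted over the list alone 4 rose. The NRF2 list's median was 0.18 (camera adjusted p = 0.00345, adjusted p = 0.194 with an estimated correlation), and the list was not called without slide 1 (0.03, adjusted p = 0.0754) or with every probe tested (0.04, adjusted p = 0.105). The calls of Aldh1a1, Ephx1 and Akr7a3 ended with array brightness as a covariate (adjusted p = 0.194, 0.119 and 0.268), at log2 changes of 1.08, 1.10 and 0.92. Over the alternatives their adjusted p ranged from 0.00276 to 0.234, 0.00518 to 0.119 and 0.0218 to 0.292.

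Transporters for sterols, organic anions and drugs rose in part. Of 25 measured hepatic transporter genes 5 rose and 0 fell: Abcg5, Abcg8, Slco1a5 (2.88-fold, SE 0.13 on the log2 scale, adjusted p = 3.02e-06), Abcb1b (2.10-fold; chosen after its values were seen) and Slco1a1 (1.95-fold, adjusted p = 5.05e-06). Slco1a5 and Slco1a1 encode uptake carriers of bile acids and other organic anions, and Abcb1b encodes a drug efflux pump. Adjusted over the list alone, 8 rose. Abcc2 and Abcc3, exporters of conjugates into bile and blood, differed by 0.43 (adjusted p = 0.0734) and 1.01 (adjusted p = 0.0961). The list's median was 0.03 (camera adjusted p = 0.000171, adjusted p = 0.0660 with an estimated correlation) and ranged from -0.02 to 0.10 over the alternatives. Slco1a4, an uptake carrier for thyroxine and digoxin, had outlier spots on 5 arrays for its brightest probe, which averaged 6.83 ± 0.18 (SD, n = 4) with fipronil and 4.60 ± 0.38 (SD, n = 6) with vehicle. Its second probe rose 5.77-fold, from 2.71 ± 0.28 (SD, n = 7) to 5.24 ± 0.19 (SD, n = 8) (adjusted p = 9.43e-09 with every probe tested).

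Genes of thyroid hormone handling were examined because glucuronidation and uptake by the liver clear thyroxine from blood. Of 18 measured genes of hormone transport, deiodination and receptors, Slco1a1 rose, shared with the transporter list, and 0 fell; adjusted over the list alone 3 rose and 3 fell. Dio1, the hepatic deiodinase, differed by -0.36 (adjusted p = 0.148) and the carrier protein gene Ttr by -0.31 (adjusted p = 0.189), the latter saturated on all 15 arrays. The median was -0.06 and the mean -0.09, whereas camera gave an upward direction (adjusted p = 0.957). Of 15 genes that T3 induces in liver, 0 passed over all genes or adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.477), and Thrsp, the classical T3-responsive gene, differed by -0.03 (adjusted p = 0.915). The Thrsp probe was saturated on 2 of 8 fipronil and 1 of 7 vehicle arrays, at mean signals of 8.30 and 8.33. Those of the saturated Ttr probe were 8.13 and 8.44, so a rise of Thrsp could hardly be seen.

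Of 30 measured genes of fatty acid oxidation that PPARalpha controls, 2 fell and 0 rose: Cyp4a8 (1.75-fold lower, log2 -0.81, SE 0.18, adjusted p = 0.0432) and Cyp4a3 (1.65-fold lower, log2 -0.72, SE 0.16, adjusted p = 0.0442), both fatty acid hydroxylases. Adjusted over the list alone, 5 fell. The median was -0.22 (camera adjusted p = 6.88e-05, adjusted p = 0.262 with an estimated correlation). Of 23 genes of glucose and amino acid metabolism, Pc, which encodes pyruvate carboxylase of gluconeogenesis, was 1.41-fold lower (adjusted p = 0.0225) and was the only member past the test over all genes or adjusted over the list alone (median -0.13, camera adjusted p = 0.115). The calls of Cyp4a8, Cyp4a3 and Pc ended with array brightness as a covariate (adjusted p = 0.282, 0.353 and 0.195), at log2 changes of -0.76, -0.60 and -0.47. That of Cyp4a8 also ended with slide as a block (-0.82, adjusted p = 0.0505), and with quantile normalization added (-0.82, adjusted p = 0.0580). Over the alternatives their adjusted p ranged from 0.0177 to 0.285, 0.0183 to 0.353 and 0.00893 to 0.282.

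Lists of other lipid pathways had 0 members past the test over all genes. For the 25 cholesterol synthesis genes the median was 0.01 (camera adjusted p = 0.796), with the smallest p for Sc5d (0.44, adjusted p = 0.116). For the 23 genes of fatty acid and triglyceride synthesis it was -0.06 (camera adjusted p = 0.572), with the smallest p for Elovl5 (-0.49, adjusted p = 0.0785), and 2 fell adjusted over the list alone. Among the 17 bile acid genes, whose median was 0.06 (camera adjusted p = 0.105), Slc10a1, the main bile acid uptake carrier, differed by 0.28 (adjusted p = 0.168) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by -0.54 (adjusted p = 0.583), which was -0.22 without fipronil replicate 7 and ranged from -0.96 to -0.20 over the alternatives. The cholesterol and bile acid lists also had 0 members past the test adjusted over the list alone.

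Messages of the receptors themselves did not pass the test. Among 24 nuclear receptors and liver transcription factors 0 passed, over all genes or adjusted over the list alone, and the median was -0.01 (camera adjusted p = 0.872, upward). Nr1i2, which encodes PXR, differed by -0.03 (adjusted p = 0.932), Nr1i3, which encodes CAR, by 0.01 (adjusted p = 0.983), and Esr1, which encodes an oestrogen receptor, by -0.59 (adjusted p = 0.141). Over the alternatives these ranged from -0.10 to 0.15, from -0.27 to 0.26 and from -0.78 to -0.10. Of 10 genes that are known to be higher in male than in female liver, Cyp3a18 and Slco1a1 rose, both shared with lists above; adjusted over the list alone 3 rose and 1 fell. Their median was 0.26 (camera adjusted p = 0.000298, adjusted p = 0.0148 with an estimated correlation). Cyp3a2, another member shared with the CAR and PXR target P450s, differed by 2.87 without passing. The list's median ranged from 0.02 to 0.39 over the alternatives. Of 9 female-predominant genes 0 passed over all genes or adjusted over the list alone, and the median was -0.25 (camera adjusted p = 0.0668). The member Sult2a1 was saturated on all 15 arrays, and the list's median ranged from -0.33 to 0.01 over 38 alternatives.

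Of 25 cell cycle genes 0 passed over all genes and 5 rose adjusted over the list alone: Ccnb2, Tyms, Cdk1, Top2a and Ccnb1. The list's median was 0.22 (camera adjusted p = 0.000709, adjusted p = 0.402 with an estimated correlation). Ccnb2, a mitotic cyclin gene, differed by 1.17 (adjusted p = 0.0509) and was above background on 8 of 8 fipronil and 1 of 7 vehicle arrays; it passed under 8 of 38 alternatives, and its change was 0.24 with normexp background correction and quantile normalization. Without slide 2 the list was not called (median 0.08, camera adjusted p = 0.153). The lists of endoplasmic reticulum stress (17 genes, median 0.08, camera adjusted p = 0.0850; Herpud1 0.19), acute phase and inflammation (21 genes, -0.18, 0.136; C3 -0.31, saturated on all arrays) and the circadian clock (16 genes, -0.16, 0.136; Bhlhe41 -1.02) had 0 members past the test over all genes or adjusted over the list alone. For the 11 perivenous genes the median was -0.13 (camera adjusted p = 0.678; Axin2 -0.25) and for the 13 periportal genes -0.15 (0.115; Aldh1b1 -0.53), with 0 past the test over all genes, and 0 and 2 that fell adjusted over the list alone.

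**Figure D4:**
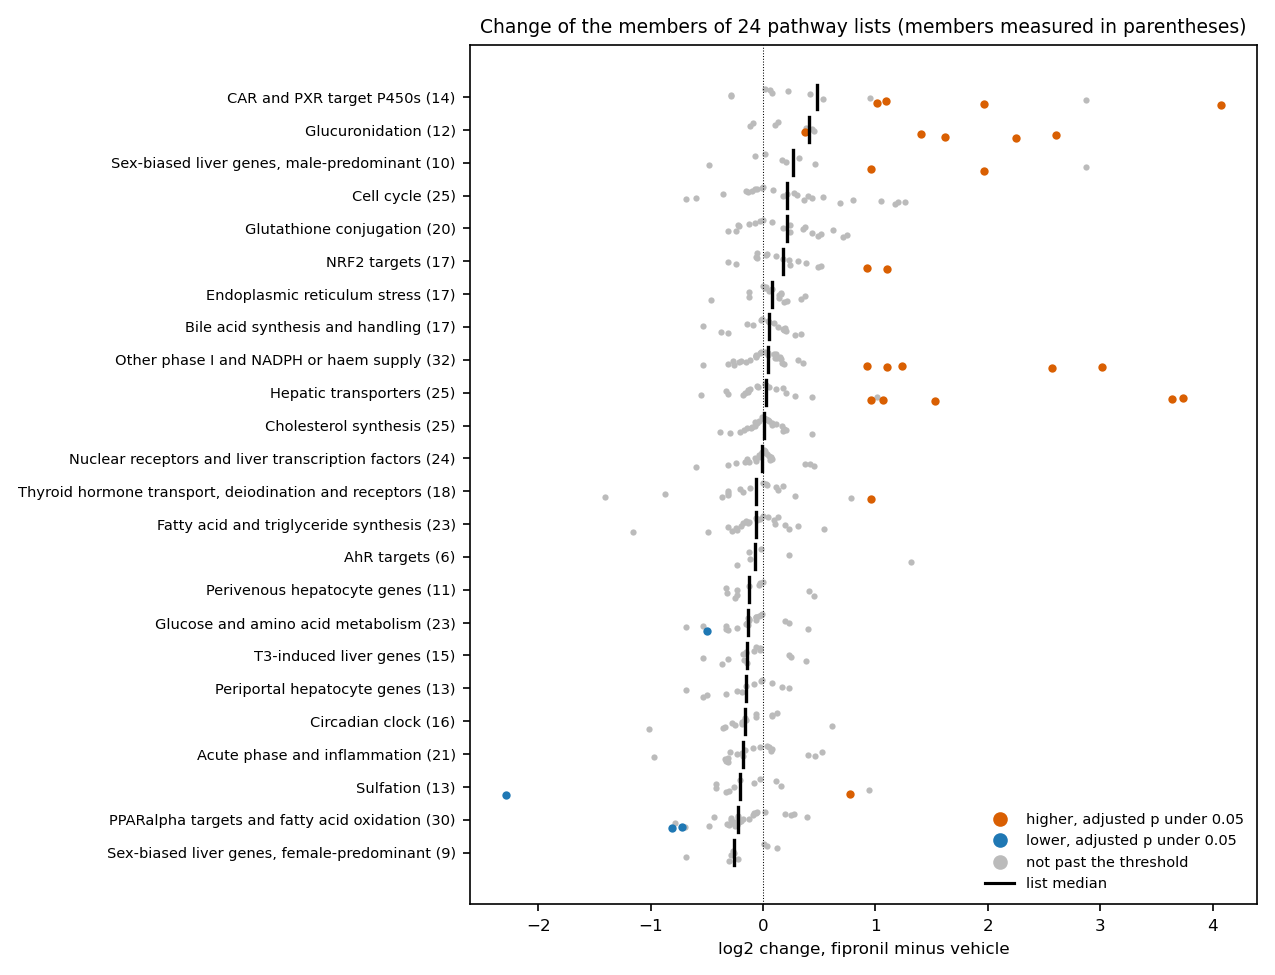
Each row is a pathway list and each point a measured member, with its log2 change (fipronil minus vehicle) on the horizontal axis, the black line at the list's median and coloured points at an adjusted p under 0.05. The median was highest for the CAR and PXR target P450s (0.48) and the glucuronidation genes (0.41). Over the alternatives these medians ranged from 0.07 to 0.81 and from 0.31 to 0.56.

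Markers of cell types were compared in the same way. Of 14 hepatocyte markers 0 passed over all genes or adjusted over the list alone, the median was -0.31 (camera adjusted p = 0.000709, adjusted p = 0.402 with an estimated correlation), and 9 of them were saturated on all 15 arrays. With quantile normalization that median was -0.02. The list shares Alb and Ttr with the thyroid hormone list, Fgb with the acute phase list, and Cps1, Ass1 and Arg1 with lists of nitrogen metabolism or zonation. Endothelial markers had a median of 0.30 over 12 genes (camera adjusted p = 0.00451, adjusted p = 0.262 with an estimated correlation); 0 passed over all genes, 3 rose adjusted over the list alone, and Stab2, a sinusoidal scavenger receptor gene, differed by 0.42 (adjusted p = 0.101). Markers of T, B and NK cells had a median of 0.48 over 7 genes (camera adjusted p = 0.0286, adjusted p = 0.402 with an estimated correlation), 0 passed over all genes or adjusted over the list alone, and Klrd1, a receptor gene of NK cells, differed by 0.95 (adjusted p = 0.174; 0.26 to 1.54 over the alternatives). Without slide 3 the endothelial list was not called (0.16, camera adjusted p = 0.0736), and with slide as a block the T, B and NK cell list was not (0.41, camera adjusted p = 0.0598). The T, B and NK cell list lost its call under 14 of 39 alternatives, among them each of slides 1, 3 and 4 left out and single arrays left out (fipronil replicate 2, 0.45, adjusted p = 0.0703; fipronil replicate 6, 0.33, 0.0503; vehicle replicate 6, 0.32, 0.114), and its median ranged from 0.18 to 0.93.

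Rgs5, a marker of pericytes, rose 2.02-fold (adjusted p = 0.00832) and was the only member of the 11 stellate cell and fibroblast genes past the test over all genes or adjusted over the list alone (median 0.04, camera adjusted p = 0.281). The 12 Kupffer cell and macrophage genes had a median of 0.20 (camera adjusted p = 0.0668), with Cd14 at 0.52 (adjusted p = 0.135). That list was called under 8 of 39 alternatives, among them slide 2 left out (0.53, camera adjusted p = 3.27e-05), and its medians on slides 1 to 4 were -0.03, -0.89, 0.06 and 1.00. The 9 cholangiocyte genes had a median of -0.14 (camera adjusted p = 0.949), with Epcam at 0.51 (adjusted p = 0.125), which passed only with slide as a block among 39 alternatives. For the 7 erythroid genes the median was -0.02 and camera pointed upward (adjusted p = 0.872). In these lists 0 members passed over all genes, and adjusted over the list alone 1 cholangiocyte gene rose. Only 2 neutrophil genes were measured, too few for a test (median 0.54), with S100a9 at 0.55 (adjusted p = 0.293). The call of Rgs5 ended with array brightness as a covariate (0.97, adjusted p = 0.108; 0.00326 to 0.187 over the alternatives), and its change was 0.55 with normexp background correction and quantile normalization.

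Of the 31 lists tested, camera called 12, with 10 upward and 2 downward. With an estimated correlation 2 calls held, those of glucuronidation and of male-predominant genes. Fry, which tests a list against no change and not against other genes, called 8 lists, and an exact permutation test of each list's mean, added after seeing the data, passed for 7 after adjustment. Over all features, 3517 of 20056 had an unadjusted p under 0.05 in limma, and counts in lists are to be read against that share. In the lists with 0 members past limma's test over all genes, such a p was found for 12 of 25 cell cycle genes. Others were 11 of 20 glutathione conjugation genes, 9 of 14 hepatocyte markers, 8 of 21 acute phase genes and 5 of 12 endothelial markers. Of the hepatocyte markers, 9 were saturated on all arrays. Such a p was found for 4 genes each of the nuclear receptor, bile acid, female-predominant and circadian lists, for 3 each of cholesterol synthesis, fatty acid synthesis, periportal and T, B and NK cell genes, and for 2 perivenous genes. The AhR, T3, endoplasmic reticulum stress, Kupffer cell and cholangiocyte lists had 1 such member each, and the neutrophil and erythroid lists had 0.

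The slides were compared because each slide was scanned as a unit. In limma's F test 488 of 20056 features differed between slides beside the effect of fipronil. With slide as a block 204 features differed between fipronil and vehicle, 114 higher and 90 lower, of which 144 were among the 175. Within slides 1 to 4, the median change of the CAR and PXR target P450s was 0.08, 1.23, -0.06 and 0.82 (0.49 with slide as a block), and that of the glucuronidation genes 0.26, 0.62, 0.58 and 0.49 (0.43). For glutathione conjugation the medians were 0.03, 0.19, 0.17 and 0.12 (0.20), for other phase I genes -0.07, 0.09, -0.04 and 0.09 (0.06), for transporters 0.13, 0.09, -0.09 and 0.20 (0.03) and for NRF2 targets 0.74, 0.04, -0.14 and 0.38 (0.13). Male-predominant genes gave 0.42, 0.41, -0.21 and 0.11 (0.27), PPARalpha targets -0.26, -0.20, -0.33 and -0.14 (-0.22), and cell cycle genes 0.26, 0.65, 0.14 and -0.06 (0.25). Hepatocyte markers gave -0.33, 0.05, -0.24 and -0.61 (-0.31), endothelial markers 0.15, -0.02, 0.44 and 0.36 (0.27), and T, B and NK cell markers 0.71, -0.34, 0.65 and 0.87 (0.41). The direction therefore held on every slide for glucuronidation, glutathione conjugation and PPARalpha targets and not for the other 9 lists. Slide 3 held 1 vehicle array, so its values rest on a single vehicle rat, and the direction differed only there for the CAR and PXR target P450s, transporters, NRF2 targets and male-predominant genes. No test was made within a slide, which held at most 4 arrays.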

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

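Of the tests in this part, only the comparison of single rats with their group was chosen before the data were seen. The tests of low signal, of dividing lymphocytes and of the spread between single rats were added once the cell cycle call was known but before their own values were, and all others only after the result was seen.

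Single rats lay far from the rest of their group in 11 of 158 groups of values tested (6.96%), where chance gives about 1 in 20; the gap to the nearest rat was divided by the group's range and exceeded Dixon's critical value at the 95% level. Fipronil replicate 2 had the highest 75th percentile intensity (269.5, next 216.5; ratio 0.627), the lowest C3 (7.79, next 8.10; 0.659), Ttr (7.81, next 8.10; 0.670) and Alas1 (7.88, next 8.17; 0.543) and the highest Sc5d (6.01, next 5.49; 0.580). The probes of C3, Ttr and Alas1 were saturated on all 8 fipronil arrays, so their low values restate the brightness of that array. Fipronil replicate 5 was lowest for Cd14 (3.04, next 3.90; 0.762) and Ugt1a2 (6.15, next 6.48; 0.575). Fipronil replicate 6 was lowest for Slco1a6 (0.64, next 1.19; 0.665) and Cyp3a2 (-5.42, next -2.66; 0.627). Vehicle replicate 3 was lowest for Cyp2b2 (1.68, next 3.22; 0.571), and vehicle replicate 7 had the lowest percentage of probes above background (50.7, next 54.6; 0.577).

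The brightest probes of Cyp2b1 and Cyp2b2 differed by 0.06 and 0.22, whereas a second probe of Cyp2b1 rose by 1.80. Saturated or missing spots are excluded, since 0 of the 30 values of these brightest probes were either. Signal shared with the abundant Cyp2b3 transcript may account for the brightest probes: over 15 arrays and deviations from the group means they correlated with the Cyp2b3 probe at r = 0.953 and 0.944 (rho 0.936 and 0.889; r without the 2 farthest arrays 0.916 and 0.859; permutation p = 1e-05 for each r, the smallest that the permutations can give, adjusted p = 2.67e-05 over 8 relations), and the second probes at r = 0.0375 and 0.364 (permutation p = 0.893 and 0.184, adjusted p = 0.893 and 0.245). More Cyp2b1 and Cyp2b2 RNA with fipronil stays open: relative to the Cyp2b3 probe of the same array the brightest probes were higher by 0.212 (exact permutation p = 0.162) and 0.374 (exact permutation p = 0.0247, adjusted p = 0.0494), and the Cyp2b3 probe was saturated on 3 arrays. Regulation in common within the gene cluster stays open beside shared signal. Probes of Cyp2b21, Cyp2b15 and Cyp2b12 correlated with the Cyp2b3 probe at r = 0.979, 0.766 and 0.492 (permutation test, adjusted p = 2.67e-05, 0.00064 and 0.101). Without the 2 farthest arrays these r were 0.960, 0.540 and 0.178. Probe sequences were not compared, so cross-hybridisation itself was not tested.

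Camera called the hepatocyte markers downward, with a median of -0.31, although 0 of 14 passed over all genes. Neither camera with an estimated correlation (adjusted p = 0.402) nor fry (adjusted p = 0.0952) gave a call. Camera's direction reversed under 4 alternatives, without a call there. Saturation on brighter arrays may account for this: a spot at the scanner's ceiling falls relative to a brighter array's 75th percentile, the 70 features saturated on all arrays had a median change of -0.31 (SD 0.0167), and log2 brightness of vehicle minus fipronil arrays was -0.31. The 9 hepatocyte markers saturated on all arrays had a median of -0.31, and the 3 saturated on none had a median of -0.0200 (from -0.23 to 0.03). Fewer hepatocytes among the cells cannot be judged from markers at the ceiling, and only 3 markers were saturated on no array. The mean changes of endothelial and cholangiocyte markers differed by 0.321 (exact permutation p = 0.114). That test does not measure the number of hepatocytes, and it had few markers and rats, so it cannot decide the question.

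Camera called the cell cycle genes upward, with a median of 0.22, although 0 of 25 passed over all genes and neither an estimated correlation (adjusted p = 0.402) nor fry (adjusted p = 0.206) gave a call. A difference in array brightness as the whole cause is argued against, because the median was 0.324 with brightness as a covariate. The camera adjusted p of 1.33e-06 there rests on the preset correlation of 0.01. Low signal by itself gave no rise, since 10000 lists matched on signal had a middle value of -0.04. The list's median stood at percentile 100 of them. They were drawn feature by feature, whereas the cell cycle genes had an estimated correlation of 0.304. That percentile therefore cannot exclude spread shared by correlated genes. Dividing lymphocytes are argued against by a negative relation between cell cycle and T, B and NK cell markers over deviations from the group means (r = -0.587, permutation p = 0.0210; rho -0.618, permutation p = 0.0155; 15 arrays), although r was -0.382 without the 2 farthest arrays, so the strength of the relation rests partly on those. Spread between single rats could account for the pattern: the difference of 0.27 in the list's mean had an exact permutation p of 0.0845 over all splits. Neither these splits nor the deviations behind r took the slides into account. A response of hepatocytes to fipronil was not tested apart from this spread.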

How the results depend on the processing

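The tests with array brightness, with slides left out, with the dimmest arrays left out, with a slide block and quantile normalization and without saturated features were chosen only after the results were seen. Of 2866 values of named genes under the alternatives, 2623 kept their side of the threshold, 203 lost their call and 40 gained one. In 0 of them did a change that passed before or after turn in direction, here termed a reversal. Of 1207 values of lists the numbers, in the same order, were 1144, 32, 27 and 4. Changes that passed neither before nor after could turn in sign and count as kept, as for Cyp2b1, Cyp2b2, Cyp1a2, Nr1i2, Nr1i3, Thrsp, Sult2a1 and Alas1. The 4 reversals were camera directions of the hepatocyte list. Its call was lost in each, and 0 were calls in the opposite direction (camera adjusted p from 0.875 to 0.984). The medians there were -0.0046 (normexp and quantile), -0.00063 (median intensity and quantile), -0.000375 (the authors' table) and -0.0036 (brightness covariate). With quantile normalization the median was -0.0176, and saturation of the list's members is weighed above. Glucuronidation and male-predominant genes were the 2 called lists that kept their call under every setting. The male-predominant median ranged from 0.02 to 0.39, and that list shares Cyp3a18 and Cyp3a2 with the CAR and PXR target P450s. With an estimated correlation 2 lists were called in place of 12. Of the 12 largest rises, 11 kept their call under every setting in which they were tested (Sbspon lost it without slide 2 and without slide 4), and of the 12 largest falls 1 did (Igfbp6). Of 39 alternatives, the call was lost in 28 for Cyp3a9, 21 each for Cyp4a8 and Akr7a3, 17 for Cyp4a3, 11 for Pc, 8 for Sult1b1, 5 for Ephx1, 4 for Aldh1a1 and 3 for Rgs5. Among the largest falls it was lost in 24 (of 38) for Slc5a5, 20 for Slc16a13, 13 for Tppp3, 7 for Rasd2, 5 for Angptl2, 4 each for Kcnk2 and Cited4, 2 each for Dlg5l17 and Stmn3, and 1 each for Sult4a1 and Gask1a. A call was gained in 12 for Gstm2, 9 (of 35) for Cyp3a2, 8 (of 38) for Ccnb2, 3 for Cd14, 2 each for Abcc2 and Abcc3 and 1 each for Bhlhe41, Elovl5, Epcam and Klrd1. Of the lists, T, B and NK cell markers lost their call in 14, hepatocyte markers in 4 beside the reversals, cell cycle, endothelial and NRF2 genes in 3 each, and CAR and PXR target P450s, glutathione conjugation, transporters, other phase I and PPARalpha targets in 1 each, the estimated correlation. Kupffer cell markers gained a call in 8, endoplasmic reticulum stress in 6, female-predominant genes in 4, acute phase, bile acid and circadian genes in 2 each, and erythroid, glucose and amino acid, and stellate cell genes in 1 each. Normexp with quantile normalization, median intensity without background subtraction and the authors' table gave smaller changes for dim genes, since an offset or remaining background narrows low signals by construction: in the same order they were 1.38, 1.59 and 1.57 for Abcg8, 0.75, 1.04 and 0.98 for Cda, 0.86, 1.07 and 1.03 for Mme, 1.42, 1.58 and 1.58 for Inmt, 1.47, 1.68 and 1.68 for Sbspon, -1.41, -1.62 and -1.62 for Kcnk2, and -0.25, -0.34 and -0.37 for Slc5a5, which alone among these lost its call in all 3. Cda and Mme had no value with a slide left out, Ccnb2 and Cyp3a2 had none under some filters or without some slides, and the hepatocyte list and its saturated genes had none without saturated features.

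Changed features, 175 with 111 higher and 64 lower, became 87 with 58 and 29 without the filter on dim probes, where 36044 features were tested and the median of all was -0.13. Lower features became 101 when signal above background was required on all arrays of a group, with 18131 features tested. With slide as a random block 303 changed and 141 were lower. With replicate number as a block, which also left out fipronil replicate 8, 90 changed, 59 higher and 31 lower, against 93 without that array alone, and Rasd2, Cyp3a9, Akr7a3, Pc and the T, B and NK cell list lost their calls. Fipronil and vehicle arrays of the same number correlated at -0.04 to 0.37, and the best partner had the same number for 3 of 7 (numbers 1, 2 and 3). For each of these 3 numbers both arrays lay on the same slide. Vehicle and fipronil arrays of 1 slide had a median correlation of 0.08, against -0.02 for different slides. A pairing of the rats was therefore neither shown nor excluded, and it cannot be told apart from a shared slide. With the brightness covariate 39 changed, 32 higher and 7 lower. Without slide 1 there were 34, 30 and 4, without slide 2 there were 114 with 71 higher, and without slide 4 there were 43, 33 and 10, with fewer arrays. Without slide 3 there were 186, with 92 higher and 94 lower. At an adjusted p under 0.01 there were 54, 40 and 14. With the covariate, lost calls went with wider errors at changes of like size (Kcnk2 -2.17, SE 0.54, in place of -2.56, SE 0.45), and for the random block the cause was not tested.

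Leaving out 1 array gave 89 to 287 changed features, 61 to 144 higher, 28 to 143 lower, and 11 to 15 lists. The changed count moved by over 1.5 times without fipronil replicates 7 (114) and 8 (93) and vehicle replicates 1 (113), 2 (89), 3 (287) and 7 (97), and the lower count also without fipronil replicates 1 (40), 3 (39) and 5 (107) and vehicle replicate 4 (41); the cause was not tested where a count rose. Signal over background limits genes silent in 1 group, such as Cda and Mme, whose folds are lower bounds, and saturation limits abundant genes, of which 70 features were saturated on all arrays.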

Other observations

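The tests of LXR, p53 and repeated sequence in this part were chosen only after the results were seen; the counts over splits were chosen before, except those over splits within slides.

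Mdm2, which encodes a p53 inhibitor, rose 1.55-fold (adjusted p = 0.000503), and Rbm38, which encodes an RNA-binding protein, rose 4.01-fold (adjusted p = 0.0221); both were chosen after their values were seen. Insig2, a regulator of sterol synthesis, rose by 0.80 and Ggt1, gamma-glutamyltransferase, by 1.55, again chosen after their values were seen. Of 2633 genes with 2 or more probes tested, 26 had a probe past the threshold; all probes passed for 5, only some for 21, and 0 had probes past it in opposite directions. For 12 genes a dimmer probe passed and the brightest did not, among them Rrm2, a ribonucleotide reductase subunit gene, at 1.24 (adjusted p = 0.0366), Cyp2b1, and Gstt2 at -0.47 (adjusted p = 0.00335).

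Activation of LXR, which induces Abcg5 and Abcg8, was a candidate explanation for their rise. The median change of 5 other measured LXR targets was 0.0986 (interval over genes -0.02 to 0.23) and 0 passed in limma, where Abca1 differed by -0.02 and Abcg1 by 0.23. These values argue against a general rise of LXR targets at the size of 0.5 asked for. The interval spans the lowest and highest of the 5 genes and does not measure the spread between rats.

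Activation of p53 was a candidate explanation for the rises of Gadd45b, Mdm2 and Rbm38. The median change of 11 other measured p53 targets was -0.167 (interval over genes -0.35 to -0.08), 1 was higher and 0 passed in limma, with Cdkn1a at -0.69 and Bax at 0.02. These values argue against a general rise of the 11 p53 targets measured. The interval leaves out Cdkn1a and Bax and does not measure the spread between rats. Activation of p53 itself was not tested and is not excluded.

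Of the 64 lower features, 9 without a symbol lay on rn4 chromosome 14 between 4398075 and 4533580, with changes from -1.90 to -1.28. A repeated sequence read by many probes may account for them: their median pairwise correlation over deviations from the group means was 0.891, against 0.142 among the other lower features. Their median correlation with Dlg5l17, whose probe lies on chromosome 8, was 0.901, and 3 further lower features elsewhere correlated with it above 0.8. The count of lower features therefore may hold several readings of 1 sequence.

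Chance can be excluded for the number of changed genes: 1 of 100 splits, the real one, gave as many (175, highest other 28). It cannot be excluded for the number of called lists, since 6 of 100 splits, the real one included, gave as many (12, highest other 14). These splits did not keep the balance of the groups on the slides. Over 100 of the 648 splits that kept each slide's numbers of both groups, 1 gave as many changed genes (175, highest other 3) and 2 gave as many called lists (12, highest other 12), the real one included in each. Chance is thereby excluded for the genes in both ways, and for the lists it stays open, because the 2 ways gave different answers. Chance can be excluded for the differences between slides: 1 of 100 assignments, the real one, gave as many (488, highest other 3).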
